A study of Homo sapiens with 8 samples.

How the data were processed

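DNA bound by EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2), was measured by chromatin immunoprecipitation on arrays (ChIP-chip) in Huh7 and PLC/PRF/5 (PLC5) hepatocellular carcinoma cells, which were untreated per the labels. Each array held immunoprecipitated (IP) DNA in one dye and input DNA of the same line in the other. The probes lie around human promoters and are spread over 2 slides that carry different probes. Each line had 2 replicates on both slides, so the 8 arrays give 4 columns of values. Per the labels, IP DNA carried Cy5 in replicate 1 and Cy3 in replicate 2 of both lines, so a replicate number is also a dye orientation. Nothing in the sources used here says whether the replicates came from separate cultures or separate immunoprecipitations, so the p-values measure the spread between these arrays, which may be technical.

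The deposited scanner files hold a spot intensity on a linear scale for each dye, already background-subtracted, detrended over the array surface and dye-normalised by Agilent Feature Extraction 9.5.3.1, per the file headers. The submitters' processing notes name version 10.5.1.1 of the same program. The authors' deposited series matrix holds log10 ratios. Each of its columns equalled the log10 ratio in the scanner file of the same array within 4.93e-06, with the sign turned for replicate 2, so its scale is log10, its direction is IP over input, as the dye labels give it, and no further centring was visible. The medians of its columns on the log10 scale were 0.00282 and 0.00559 for slides 1 and 2 of Huh7 replicate 1, 0.00335 and 0.00564 for Huh7 replicate 2, -0.000412 and -0.00195 for PLC5 replicate 1, and 0.00121 and 0.00367 for PLC5 replicate 2. The genome build behind the probe coordinates is not given in the sources used here, and coordinates are printed as the array files give them.

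The slides carried 237210 and 237201 probes that are not controls. Between 94.1% and 98.7% of them were well above background in both channels of an array, between 29 and 135 per array were set aside because the scanner software marked them as outliers, and between 9 and 174 were saturated and kept. For each spot, log2 of the IP over the input processed signal was taken from the dye labels and centred on the median of its array, with no loess or quantile step, because a large share of probes may truly shift in a ChIP experiment. The value of a promoter was the mean over all probes that the files assign to one gene and annotate as upstream of, inside or downstream of it, with at least 5 probes required. This left 17027 promoters with 452182 probes and a median of 25 probes each, and 560 named features fell under the minimum. Symbols were updated through the RefSeq accession for 16077 promoters, 3071 of which changed name. The file's name is used in the text, with the present symbol in brackets where it differs. Errors come from the spread between arrays, of which each line has 2 per slide.

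Promoter values were fitted with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8. The mean of each line was tested against 0 and the lines against each other in one fit of all 4 columns, with moderated variances and Benjamini-Hochberg adjustment over all promoters at 0.05, two-sided. That fit had 2 residual and 5.75 prior degrees of freedom. Replicate numbers mark the dye orientation, a factor that the labels give, so a fit with the replicate number as a block was made as well. Over promoters, the deviations of same-numbered replicates from their line means correlated at 0.102 between the lines. The blocked fit had 1 residual degree of freedom, and limma then used 1 spread for every promoter. Blocked p-values of promoters therefore do not measure the spread of the single promoter. Arrays were scanned on 2 dates, the first with Huh7 replicate 1 and PLC5 replicate 2 and the second with Huh7 replicate 2 and PLC5 replicate 1, so scan date was also fitted as a block and differences are given within each date. Within a date the lines had opposite dye orientations, so a within-date difference mixes line with dye. Every adjusted p from a promoter or a window below is from limma.

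For bound regions, the mean over all probes within 500 bp of each probe, with at least 3 probes, was tested the same way in 426446 windows. A region counted as bound at an adjusted p under 0.05 and a mean log2(IP/input) of at least 1, and as depleted at a mean of -1 or lower, with windows within 500 bp merged. Gene lists were tested against all other promoters with camera of limma, at a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over 21 lists. Overlap between lines was tested with Fisher's exact test. The 5 Wnt antagonists of the study were taken from general knowledge of this study, which was not checked, since the records used here do not name them. The list may therefore not be independent of the samples. Samples, designs, gene lists and most alternatives were fixed before the data were examined, and those chosen later are named as such.

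The genes named were fixed by rule. In each line these were the 10 highest promoters past the threshold, and between lines the 8 highest and 8 lowest differences. Where fewer than 3 passed, they were the 5 with the smallest p in each direction. In every comparison AXIN2, NKD1, PPP2R2B, PRICKLE1, SFRP5, MYT1, CNR1, KCNA1, WNT1, ACTB, GAPDH and EZH2 were added, with 2 to 4 members of each list. Promoters and regions named from the blocked fits were chosen after their values were seen.

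The procedure was tested on simulated data for the Huh7 comparison, with 17027 promoters and 50 changed at each size, under 2 settings of the spread. With the spread drawn from the fitted prior and no block it recovered 5 at a log2 change of 0.25, 47 at 0.5, and 50 at 1 and at 2, with 12 false among 164 calls. With the block, 4, 48, 50 and 50 were recovered, and 24 of 176 calls were false. With the Huh7 arrays alone, 29 of 183 calls were false. When each promoter instead kept its own estimated spread, 25 were recovered at 0.25 without the block, 32 with it and 35 with the Huh7 arrays alone, and 50 of 50 at each larger size. False calls were then 17 of 192, 30 of 212 and 40 of 225. The window test found 95 of 100 planted regions of log2 1.5 and called 0 regions off target. Noise was drawn independently for each probe there, so this recovery does not carry over to the data. On the real arrays 8 Huh7 windows averaged -1.5 or lower, and the fit without a block called 0 regions at that minimum. The list test with the preset correlation found 5 of 5 lists raised by 0.1 and called 0 of the others, whereas with the estimated correlation it found 0 of the 5. Promoters of these simulated lists were drawn independently. In the data the estimated correlation ranged from -0.244 (Wnt antagonists of the study) to 0.413 (housekeeping genes). The simulation therefore does not give the rate of false lists in the data. Alternatives covered the background correction (normexp with an offset of 50), loess within arrays, one scale for all arrays, the series matrix, a filter on dim probes, the promoter summary, the probe minimum, a variance trend, separate slides, blocks, the size of the fold or region minimum, the window width and leaving out each replicate. The normexp setting started from raw spot means, so it also left out the detrending and dye normalisation of the processed signals. It therefore changed more than the background. A correction for probe base composition was not run, because neither probe sequences nor a genome were used here.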

Results

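EZH2 occupancy was measured at human promoters in Huh7 and PLC5, both established human hepatocellular carcinoma cell lines, to find the genes that EZH2 binds under normal growth conditions. Each line was represented by 2 replicates of opposite dye orientation. Values are log2(IP/input) per promoter, so that 0 is the median probe of an array, values above 0 are enriched in the IP and values below 0 are depleted from it. Between 94.1% and 98.7% of probes per array were well above background in both channels. The spread over the 17027 promoters (SD) was 0.121 and 0.133 in Huh7 replicates 1 and 2, and 0.151 and 0.0699 in PLC5 replicates 1 and 2.

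The Huh7 replicates ranked promoters alike, and the PLC5 replicates ranked them in opposing order. Across promoters, which are not independent replicates, the Huh7 replicates correlated at r = 0.83 (Spearman 0.82) and had the same sign at 81.2% of promoters. The PLC5 replicates correlated at r = -0.40 (Spearman -0.42), with the same sign at 33.6%. Over single probes the correlations were 0.66 in Huh7 and -0.18 in PLC5. Between the lines, arrays of the same dye orientation correlated at 0.0040 for replicate 1 and 0.24 for replicate 2, and arrays of the same scan date at 0.20 and -0.039. A PLC5 mean is therefore the mean of 2 opposing patterns, of which replicate 1 has the wider spread.

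**Figure D1:**
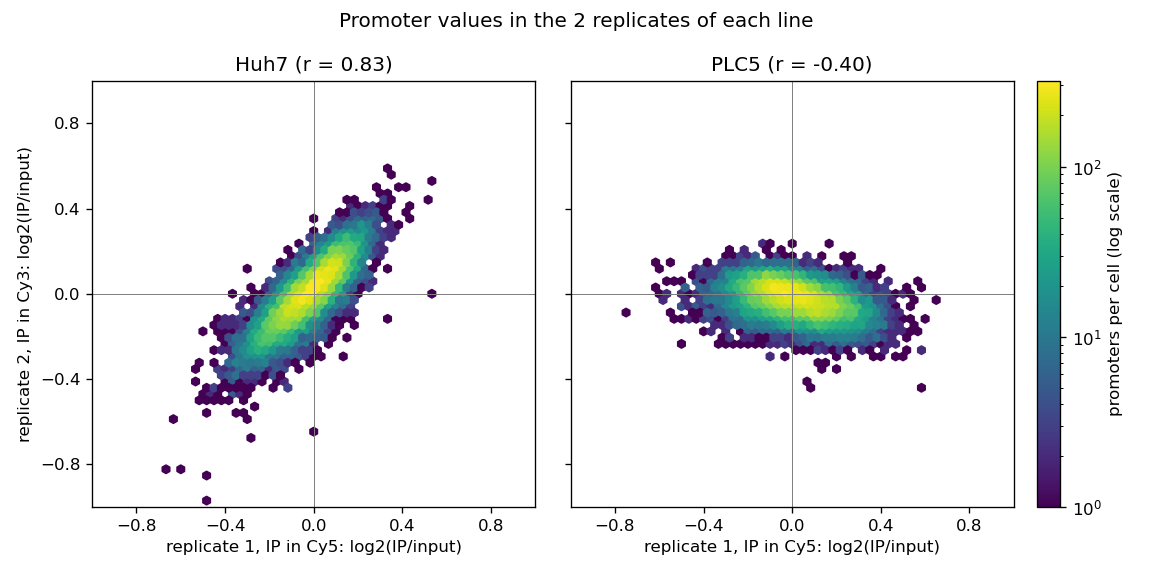
Promoter log2(IP/input) of replicate 1 (IP in Cy5, x axis) against replicate 2 (IP in Cy3, y axis) for Huh7 and PLC5, where the colour gives the number of promoters per cell on a log scale. The 17027 promoters lie along a rising line in Huh7 (r = 0.83) and along a falling one in PLC5 (r = -0.40).

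In Huh7, with IP and input assigned by the dye labels, the promoters furthest from the array median lay below it rather than above it. With the replicate as a block, CCND2, which encodes the cell cycle regulator cyclin D2, had the lowest value, -0.74 ± 0.10 (SD, n = 2; limma adjusted p = 1.14e-19). BMI1, a subunit of Polycomb repressive complex 1, followed off chromosome Y at -0.60 ± 0.046, and the transcription factor gene OVOL2 at -0.52 ± 0.060. At the other end, ALG1, which encodes a mannosyltransferase of N-glycan synthesis, had 0.52 ± 0.0023, POMGNT1, an enzyme of dystroglycan glycosylation, 0.47 ± 0.043, and KDELR1, a receptor that returns proteins to the endoplasmic reticulum, 0.46 ± 0.076. The ALG1 value rested in part on 1 probe, which read 1.33 and 1.56 in the Huh7 replicates, against 0.75 and 0.60 at the next highest. Further high values were 0.45 at hsa-mir-616, 0.45 at THOC5, 0.45 at hsa-mir-127, 0.43 at IFITM3, 0.40 at GON4L, 0.40 at TMEM116 and 0.39 at LRRC40. Further low values were -0.51 at FRAS1, -0.49 at KRTAP19-6, -0.48 at PELI2 and -0.48 at hsa-mir-513-1. RBMY1J, RBMY1D and LOC728137 (TSPY3) on chromosome Y reached -0.72, -0.73 and -0.67, and they belong to multi-copy families whose probes can bind DNA from several copies.

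Without the block, 0 promoters were enriched and 0 depleted in Huh7 at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05, 1767 lay above 0 and 2102 below, and the smallest adjusted p was 0.0663. The promoters with the smallest p, none of which passed, were POMGNT1, KDELR1, TMEM116, ACA3 (0.38) and C10orf65 (HOGA1; 0.36) above 0, and RBMY1J, OVOL2, SLC1A2 (-0.44), HS6ST3 (-0.46) and FRAS1 below 0. With the replicate block, 435 promoters were enriched and 899 depleted in limma, and with the scan date as a block 381 and 809. Both blocked fits used 1 spread for every promoter. Their median standard errors were larger than without a block (0.0734 and 0.0748 against 0.0598). The 2 pairs of counts share the same Huh7 means, so neither is separate evidence for the other. If IP and input were exchanged in both Huh7 replicates, each Huh7 sign above would turn, and the blocked fit with these replicates turned gave 809 enriched and 381 depleted. The count moved with the arrays in the fit, which also set its degrees of freedom: without either PLC5 replicate it was 3943 enriched and 4064 depleted, and without Huh7 replicate 1 or 2 it was 0 enriched in both cases and 7 or 2 depleted.

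The 5 promoters listed as the Wnt antagonists of the study lay below 0 on average in Huh7. PRICKLE1, a regulator of Wnt and planar cell polarity signalling, was the lowest at -0.47 ± 0.0018 (SD, n = 2), with a limma adjusted p of 0.0663, or 1.43e-07 with the replicate block. PPP2R2B, a regulatory subunit of protein phosphatase 2A, had -0.16, the Dishevelled inhibitor NKD1 -0.12, the secreted Frizzled-related protein SFRP5 -0.050 and AXIN2 of the beta-catenin destruction complex -0.037, and none of these 4 passed with or without the block. SFRP5 differed in sign between the Huh7 replicates. Without the block, 0 of the 5 passed over all promoters and 2 when adjusted over the list alone. With the block, PRICKLE1 alone passed in both, and since the list is held to be the study's own choice, the count is not independent evidence of its direction.

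Among promoters often used as positive controls for PRC2, WNT1 had -0.27 ± 0.012 (SD, n = 2; limma adjusted p = 0.0752, and 0.00861 with the replicate block), KCNA1 -0.18, MYT1 -0.057 and CNR1 -0.011. The last 3 passed neither fit. The housekeeping promoters ACTB and GAPDH had 0.088 and 0.10, and EZH2 itself -0.13, with limma adjusted p values of 0.363, 0.299 and 0.198.

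**Figure D2:**
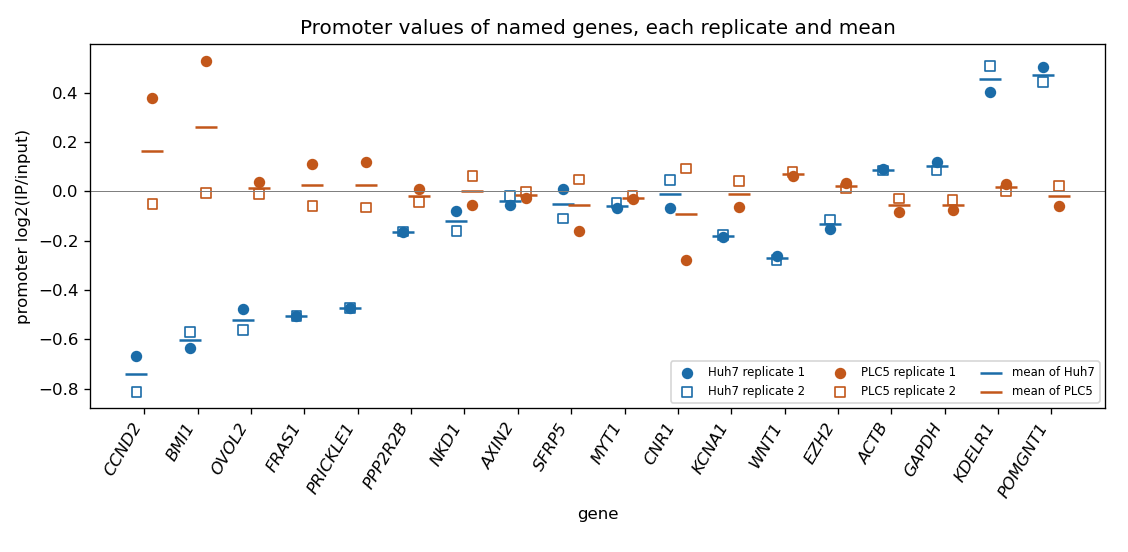
Promoter log2(IP/input) (y axis) of 18 named genes (x axis) in each replicate of Huh7 and PLC5, with filled circles for replicate 1, open squares for replicate 2 and bars for the mean. CCND2 lay at -0.67 and -0.81 in the Huh7 replicates, and at 0.38 and -0.049 in the PLC5 replicates.

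Of the 21 gene lists, 9 stood apart from other promoters in Huh7 with the preset correlation, 8 lower and 1 higher. These are not 9 separate results, since 13 of the 16 PRC2 control loci and all 5 Wnt antagonists of the study are also in another list. Olfactory receptor promoters, whose genes are silent outside sensory tissue, had a median of -0.15 over 296 promoters, 250 of them below 0 in both replicates (camera adjusted p = 2.93e-23, and 0.67 with an estimated correlation). After normexp that median was -0.0079, and after loess it was -0.075. None of these promoters passed over all promoters, 98 were lower when adjusted over the list alone, and 77 were depleted with the replicate block, among them OR10G7 (-0.45), OR5T2 (-0.44) and OR5L2 (-0.44). Developmental transcription factors, a class that PRC2 commonly represses, had a median of -0.064 over 165 promoters, 108 of them below 0 in both replicates (adjusted p = 2.41e-05, and 0.703 with an estimated correlation). Of these, 16 were depleted with the block and 14 were lower without it when adjusted over the list alone, with TBX5 at -0.35, EMX1 at -0.34, DBX1 at -0.32 and SOX14 at -0.32. The PRC2 control loci had a median of -0.10, with 13 of 16 below 0 in both replicates (adjusted p = 0.00153, and 0.67 with an estimated correlation), and CCND2, GATA6 (-0.30) and WNT1 were depleted with the block.

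Protocadherins (median -0.086, adjusted p = 0.0029), histone gene clusters (-0.067, 0.00365), neuronal channels and receptors (-0.038, 0.00363), the Wnt antagonists of the study (-0.12, 0.0215) and the wider list of Wnt antagonists and negative regulators (-0.029, 0.0325) were also lower in Huh7. Housekeeping promoters were higher (0.063, 0.0215). After normexp the medians of these lists, in the order given, were -0.044, -0.061, -0.041, -0.12, -0.040 and 0.037. With an estimated correlation the adjusted p values of these 6 lists were 0.67 for both Wnt antagonist lists and 0.845 for the others. Depleted members with the block included PCDHA3 (-0.34), HIST1H4L (H4C13; -0.41), the calcium channel subunit gene CACNG2 (-0.41), and the Wnt antagonists DACT1 (-0.36) and WIF1 (-0.27), while the wider Wnt list member SENP2 and the housekeeping gene NDUFA1 were enriched (0.22 and 0.26). Without Huh7 replicate 1 the wider Wnt list and the housekeeping list no longer passed (adjusted p = 0.0543 and 0.0564). With the estimated correlation 0 of 21 lists passed in any comparison.

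The other 12 lists did not stand apart in Huh7. HOX clusters, among the best known PRC2 targets, had a median of 0.0082 over 39 promoters (adjusted p = 0.642), which turned to -0.0091 with normexp, and 0 of them passed with the block. Wnt ligands had -0.019, hepatocyte genes -0.0076, chemokines and interleukins -0.0083 and Polycomb complex subunits -0.0054, and with the series matrix values these became 0.0025, 0.014, 0.013 and 0.016. Those values are not centred, and the median of all promoters moved with them from 0.0018 to 0.023, so the 4 lists kept their place relative to all promoters. For chemokines the median was also above 0 with loess (0.0015), where that of all promoters was 0.016. Tumour suppressors had 0.019, metallothioneins 0.060 and blood cell genes 0.015, which turned to -0.00029, -0.024 and -0.017 with normexp. Zinc finger genes had 0.0012, which turned to -0.00066 with all arrays on one scale. Keratins had -0.023, ribosomal proteins 0.029 and fibroblast genes 0.016. With loess, Wnt ligands and keratins were lower as well (adjusted p = 0.00457 and 0.00929, against 0.181 for both without it), and their adjusted p with an estimated correlation, without loess, was 0.845. Single members of these lists passed with the block, among them FOXA2 (-0.29), GC (-0.29), SUZ12 (-0.22), RPLP1 (-0.25), LUM (-0.25), KRT6C (-0.39), ZNF681 (-0.42), WNT6 (-0.26), IL6 (0.26), MT1M (0.23) and GSTP1 (0.23).

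**Figure D3:**
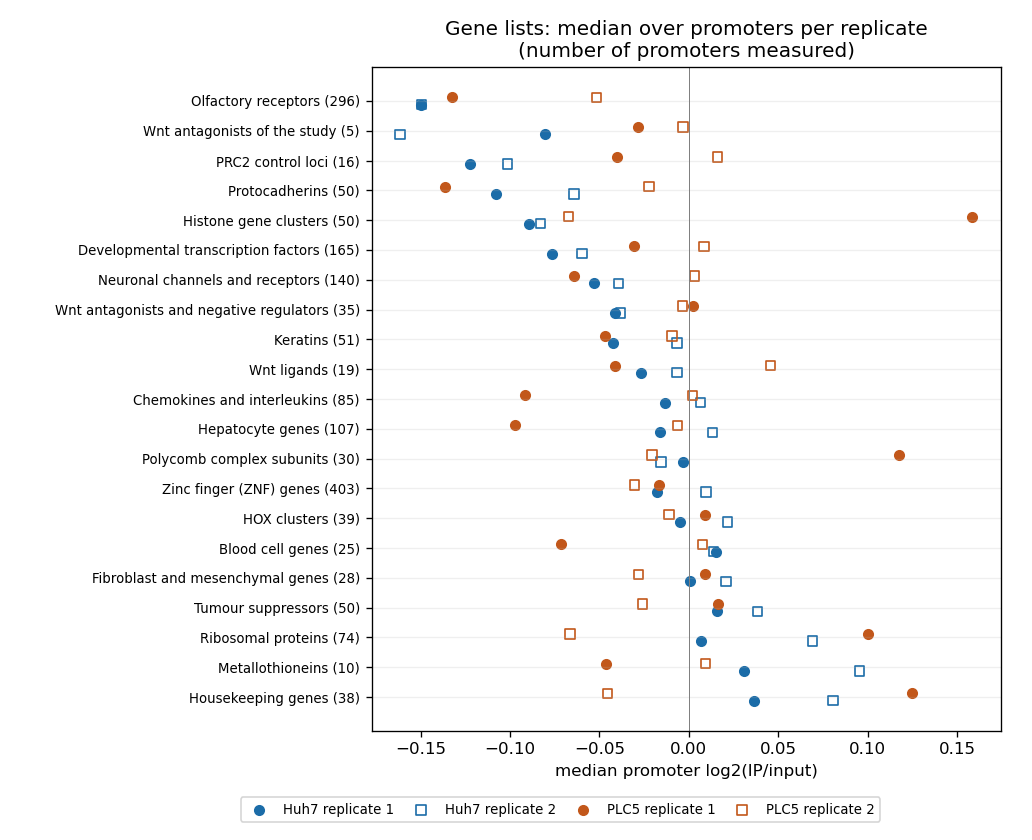
Median promoter log2(IP/input) (x axis) of the 21 gene lists (y axis, with the number of promoters measured) in each replicate of Huh7 and PLC5. The Huh7 replicates lay close together, with olfactory receptors at -0.15 in both, whereas PLC5 replicates differed in sign for histone gene clusters (0.16 and -0.067) and housekeeping genes (0.12 and -0.045).

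At the level of regions, 0 bound and 0 depleted regions were called in Huh7 by limma without the block among 426446 windows. At an unadjusted p under 0.05 and the same minimum there were 0 bound and 33 depleted regions. In the fit with the replicate block 0 were bound and 33 depleted, and with both Huh7 replicates turned in sign 33 were bound and 0 depleted. The repeated 33 is set by the minimum on the Huh7 mean, which neither a block nor the PLC5 arrays change. Without Huh7 replicate 1 the fit gave 10 bound and 59 depleted regions, without replicate 2 it gave 5 and 46, and without either PLC5 replicate 0 and 33. Places are given here with their extent at a minimum of 1.5-fold, which is wider than the part at -1 or lower. The deepest off chromosome Y lay inside BMI1 (chromosome 10, 22651096 to 22652140), at -1.35 ± 0.11 (SD, n = 2) in its lowest window. Next came 2 of these wider stretches at CCND2 on chromosome 12, one upstream (4247993 to 4251246; -1.29 ± 0.26) and one inside the gene (4253797 to 4255398; -1.20 ± 0.17). Others were found upstream of the stress-response factor gene ATF3 (chromosome 1, 210845452 to 210847678; -1.11), inside FRAS1 (chromosome 4, 79196762 to 79199064; -1.13), upstream of MGST1 (-1.17) and the Nodal and Wnt antagonist gene CER1 (-1.13), and inside PRLR (-1.06) and ID4 (-1.01). In the other direction, no window averaged 1 or more in Huh7. With the block and a minimum of 1.5-fold, 349 regions were enriched and 1044 depleted, of which 0 and 37 were on chromosome Y. The highest enriched ones were near FAM120B (0.97), FUCA2 (0.96) and FAM102A (0.95).

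**Figure D4:**
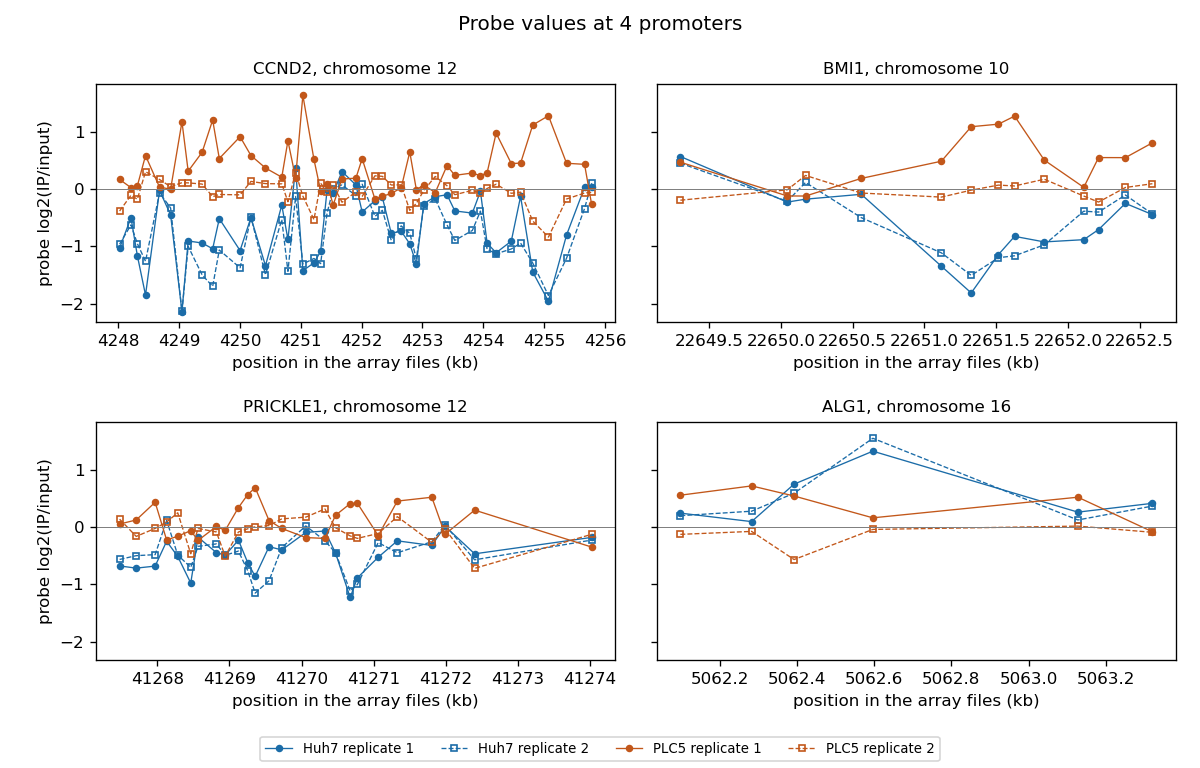
Log2(IP/input) of single probes (y axis) by position in kb as the array files give it (x axis) at CCND2, BMI1, PRICKLE1 and ALG1, with 1 line for each replicate of Huh7 and PLC5. At BMI1 and CCND2 the Huh7 replicates dip together where PLC5 replicate 1 lies above 0, as in the lowest BMI1 window (-1.43 and -1.27 in Huh7, 0.91 and -0.027 in PLC5).

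In PLC5, olfactory receptor promoters were lower than other promoters, with medians of -0.13 and -0.052 in the 2 replicates and 200 of 296 promoters below 0 in both (camera adjusted p = 7.27e-31, and 0.779 with an estimated correlation). The median over both replicates was -0.091, and -0.018 after normexp. With PLC5 replicate 2 turned in sign the median was -0.044, 53 promoters lay below 0 in both replicates, and the list was still lower (adjusted p = 7.61e-06, and 0.704 with an estimated correlation). Which replicate would be the exchanged one is not known. Turning replicate 1 instead would give the same values with the opposite sign, so the direction under an exchange stays open. Protocadherins (median -0.081, adjusted p = 6.94e-12), hepatocyte genes (-0.055, 3.25e-06), chemokines and interleukins (-0.044, 1.47e-05), neuronal channels and receptors (-0.023, 0.00281) and zinc finger genes (-0.022, 0.00281) were lower as well. Polycomb complex subunits (0.043, 0.00281), housekeeping genes (0.040, 0.00703) and histone gene clusters (0.042, 0.0164) were higher. With an estimated correlation the adjusted p values of these 8 lists lay between 0.779 and 0.892. After normexp, which moved the median of all promoters to 0.016, the lower lists in this order had medians of -0.019, -0.0097, -0.020, -0.0018 and -0.0017.

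The PLC5 list results other than that of the olfactory receptors rested on replicate 1. Without it, olfactory receptors stayed lower (adjusted p = 0.00319), housekeeping and histone promoters turned to lower (0.0431 and 0.00319), and the other 6 lists no longer passed (0.281 for hepatocyte genes, 0.748 for Polycomb subunits, 0.159 for neuronal genes, 0.242 for chemokines, 0.367 for zinc finger genes and 0.748 for protocadherins). With all arrays on one scale, housekeeping, histone and neuronal genes no longer passed (0.212, 0.508 and 0.0977), nor did histone genes with loess (0.0547). With PLC5 replicate 2 turned in sign zinc finger genes did not pass (0.332), and 12 lists passed in all. With the replicate block, ribosomal proteins were also higher (0.027, adjusted p = 0.0158, against 0.0565 without) and blood cell genes lower (-0.051, 0.0398, against 0.0525), and the blocked adjusted p with an estimated correlation was 0.932 and 0.866. Without replicate 1 the ribosomal proteins were lower instead (0.00319), Wnt ligands were higher (0.00344), and developmental transcription factors were higher (0.00319), whereas without replicate 2 the last were lower (0.0315). The remaining 10 lists passed neither fit in PLC5. Their medians were -0.015 for the PRC2 control loci, 0.0058 for HOX clusters, -0.0050 for developmental transcription factors, -0.0046 for Wnt ligands, -0.016 for the Wnt antagonists of the study, 0.00080 for the wider Wnt list, 0.0027 for tumour suppressors, -0.027 for keratins, -0.016 for metallothioneins and -0.015 for fibroblast genes. Among these, the sign of HOX clusters, developmental transcription factors, Wnt ligands, both Wnt antagonist lists, tumour suppressors and fibroblast genes changed with at least 1 other scaling, some of which also moved the median of all promoters in PLC5 (to 0.016 with normexp and -0.0072 with all arrays on one scale).

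Among single promoters in PLC5, 0 were enriched and 0 depleted in limma, with 75 above and 368 below 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.992. When the replicate was a block, 0 were enriched and 3 depleted, hsa-mir-224 (-0.42 ± 0.45, SD, n = 2; limma adjusted p = 0.000213), hsa-mir-512-1 (-0.37 ± 0.20; 0.00451) and the lipase gene LIPI (-0.33 ± 0.31; 0.0366). These p-values rest on 1 spread for every promoter and leave out the promoter's own SD, which was larger than the mean for hsa-mir-224 and close to it for LIPI. With the scan date as a block 0 were enriched and 2 depleted. The promoters with the smallest p, which did not pass, were the interferon receptor gene IFNAR1 (0.21), FLJ40606 (0.20), AP2A1 (0.21), DKFZp666G057 (SAXO2; 0.26) and LPAL2 (0.21) above 0, and hsa-mir-512-1, OR8H1 (-0.28), TAS2R48 (TAS2R19; -0.27), OR5H1 (-0.23) and hsa-mir-513-1 (-0.25) below 0. PRICKLE1 had 0.027 ± 0.13, NKD1 0.0034, AXIN2 -0.016, PPP2R2B -0.017, SFRP5 -0.056, WNT1 0.070, KCNA1 -0.010, MYT1 -0.025, CNR1 -0.092, ACTB -0.055, GAPDH -0.054 and EZH2 0.023, and none of these 12 passed. Without PLC5 replicate 1 limma called 9 enriched and 244 depleted promoters, and without replicate 2 it called 3943 and 2698, each resting on a lone array assumed to vary like the Huh7 arrays. No region was bound or depleted in PLC5, where 0 regions reached the minimum at an unadjusted p under 0.05 in limma. Without replicate 1 there were 1 bound and 2 depleted regions, and without replicate 2 there were 28 and 72.

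The lines were compared because the same assay was run in both. Histone gene clusters, developmental transcription factors, olfactory receptors and the PRC2 control loci were higher in PLC5 than in Huh7, with median differences (PLC5 minus Huh7) of 0.12, 0.046, 0.051 and 0.040. Their camera adjusted p values were 0.000242, 0.0005, 0.00089 and 0.0109, and each was 0.871 with an estimated correlation. Under the other scalings the histone difference ranged from 0.068 with loess to 0.13 with normexp. The olfactory receptor difference turned to -0.0069 with loess and to -0.017 with normexp, where the median difference of all promoters was -0.015 and 0.021, and it no longer passed with loess (adjusted p = 0.431). Within the first scan date the differences were 0.046, 0.076, 0.099 and 0.14, and within the second 0.20, 0.019, 0.0053 and -0.0074, so that of the PRC2 control loci changed sign between dates. The dates hold different replicates of each line in opposite dye orientations, so date, dye and replicate cannot be told apart here. With the scan date as a block the adjusted p values were 5.17e-06, 0.00264, 0.00647 and 0.00177. Without PLC5 replicate 1 the histone list no longer passed (adjusted p = 0.227), and without PLC5 replicate 2 the other 3 did not (0.464, 0.695 and 0.376), with the olfactory receptors turned to lower. With PLC5 replicate 2 turned in sign, histone genes and olfactory receptors were still higher in PLC5 (1.46e-05 and 0.000319). Developmental transcription factors and the PRC2 control loci did not pass (0.258 and 0.305). With an estimated correlation the adjusted p was 0.974 for each. Turning PLC5 replicate 1 instead would reverse the turned PLC5 values, and that comparison was not run. With both Huh7 replicates turned in sign 11 lists passed, the PRC2 control loci, developmental transcription factors and olfactory receptors as lower in PLC5 (0.00114, 5.3e-05 and 3.51e-40), and histone genes did not (0.185). With an estimated correlation the adjusted p of these 4 was then 0.668, 0.668, 0.668 and 0.766.

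With the replicate block, Polycomb complex subunits (0.057; within dates -0.012 and 0.14) and the Wnt antagonists of the study (0.12; within dates 0.12 and 0.11) were also higher in PLC5, with adjusted p values of 0.0204 and 0.0388 against 0.169 and 0.0606 without it, and 0.966 for both with an estimated correlation in the blocked fit. Of the 5 Wnt antagonists, 1 (PRICKLE1) passed over all promoters with the block, and without it 0 passed over all promoters and 1 when adjusted over the list alone. That list is not independent evidence of its direction. The other 15 lists did not differ between lines at the threshold, with median differences from -0.11 for metallothioneins to 0.058 for the wider Wnt list, which passed with loess and with all arrays on one scale (adjusted p = 0.0295 and 0.0207). With loess, Wnt ligands (0.0206) and the study's Wnt antagonists (0.0169) also passed, the latter on one scale too (0.0295). Without PLC5 replicate 1, the study's Wnt antagonists, the wider Wnt list, Wnt ligands, neuronal genes and protocadherins were higher in PLC5 (0.00337, 0.00401, 0.0032, 0.000167 and 0.00401), and housekeeping and ribosomal genes lower (0.000335 and 0.000645). Without PLC5 replicate 2, Polycomb subunits were higher (0.0158), and protocadherins, hepatocyte genes and chemokines lower (0.0108, 0.00176 and 0.00266). Without Huh7 replicate 1 or 2, Polycomb subunits were higher (0.0181 or 0.0433), and without Huh7 replicate 1 so were the study's Wnt antagonists (0.0184). In the estimated-correlation test with all arrays the adjusted p of these lists was 0.871 or 0.877.

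At single promoters, CCND2 differed most with the dyes as labelled, at 0.91 higher in PLC5 (limma SE 0.14 without and 0.10 with the block), with differences of 0.62 and 1.19 within the 2 scan dates. BMI1 was next at 0.86 (0.63 and 1.1 within dates), then RBMY1J at 0.79, LOC728137 (TSPY3) at 0.66, LPAL2 at 0.64, RBMY1D at 0.62 and PELI2 at 0.60. PRICKLE1 differed by 0.50 (0.41 and 0.59 within dates; blocked limma adjusted p = 0.00168), EMX1 by 0.43, DACT1 by 0.37 and HIST1H2BG (H2BC8) by 0.39. Promoters that lay lower in PLC5 included hsa-mir-127 (-0.54), POMGNT1 (-0.49), hsa-mir-224 (-0.48; -0.030 and -0.93 within dates), IFITM3 (-0.48) and ZNF552 (-0.47). These passed with the replicate block, where 112 promoters were higher and 53 lower in PLC5 (95 and 45 with the scan date as a block). With both Huh7 replicates turned in sign, CCND2 lay at -0.58 and the furthest differences were -0.84 at RBMY1D and 0.65 at ALG1, with 76 promoters higher and 352 lower in the blocked fit. In limma without a block 0 were higher and 0 lower, with 999 and 927 at an unadjusted p under 0.05 and a smallest adjusted p of 0.397. The promoters with the smallest p there, none of which passed, were RBMY1J, LPAL2, OVOL2 (0.54), CCND2 and FRAS1 (0.53) in one direction, and POMGNT1, TMEM111 (EMC3; -0.45), AKAP14 (-0.44), C10orf65 (HOGA1; -0.43) and KDELR1 (-0.44) in the other. Differences at the other named promoters were 0.34 for WNT1, 0.17 for KCNA1, 0.16 for EZH2, 0.15 for PPP2R2B, 0.12 for NKD1, 0.033 for MYT1, 0.022 for AXIN2, -0.0067 for SFRP5, -0.081 for CNR1, -0.14 for ACTB and -0.16 for GAPDH. Without PLC5 replicate 1, 998 promoters were higher and 1328 lower, and without replicate 2, 4373 and 3305; without Huh7 replicate 1 or 2, 5 or 2 were higher and 0 lower in both cases.

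No promoter was enriched in both lines. With 0 promoters enriched in each, Fisher's exact test gave p = 1 and carries no information. With the replicate block 1 promoter, LIPI, was depleted in both, against 0.158 for independent lists (Fisher's exact test, two-sided p = 0.150). Without PLC5 replicate 1, 2 promoters were enriched in both lines (2.08 for independent lists), and without PLC5 replicate 2 there were 634, fewer than the 913 for independent lists (Fisher's exact test, p = 4.28e-35, over promoters rather than replicates).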

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

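All tests of explanations in this part were chosen after the results were seen. Differences between the lines were examined because the 2 cell lines went through the same assay, and 4 gene lists passed the test of that difference. Median differences (PLC5 minus Huh7) were 0.12 for histone gene clusters, 0.046 for developmental transcription factors, 0.051 for olfactory receptors, which turned to -0.0069 with loess and -0.017 with normexp, and 0.040 for the PRC2 control loci. None passed with an estimated correlation (adjusted p = 0.871 for each). Under the other scalings the histone difference ranged from 0.068 with loess to 0.13 with normexp. Without PLC5 replicate 1 the histone difference no longer passed (adjusted p = 0.227), and without PLC5 replicate 2 the other 3 did not (0.464, 0.695 and 0.376).

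The first pattern is that the PLC5 replicates ranked promoters in opposing order. A dye effect shared by both lines would make the differences between replicates correlate between Huh7 and PLC5. They did so at 0.215 after correction for probe noise, too little for that effect to be the whole cause. With replicate 2 turned in sign the corrected correlation of the PLC5 replicates was 0.602. Turning 1 replicate only reverses the sign of the negative correlation. This value therefore cannot show an exchange of IP and input in 1 PLC5 replicate. The same correction gave a value above 1 for Huh7 (1.14), so it overshoots, and the exchange stays open with 2 arrays per slide.

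The second pattern is that known PRC2 target promoters lay below the array median in Huh7, where an EZH2 IP would be thought to raise them. A trend with spot brightness was argued against as the whole cause, since after loess the median of the developmental transcription factors was still -0.0761 relative to all promoters. IP and input may have been exchanged in both Huh7 replicates: 288 windows lay below -0.75 in both and 19 above 0.75. Developmental transcription factors lay -0.066 from all promoters and HOX promoters, which the exchange would also lower, 0.0064, so this stays open. Probe base composition could not be examined without sequences, and no biological explanation was tested.

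The third pattern is that no Huh7 promoter passed in limma at an adjusted p under 0.05 without a block, with 1767 above and 2102 below 0 at an unadjusted p under 0.05, although the Huh7 replicates correlated at 0.83. The spread between the PLC5 replicates enters the variances of that fit and may account for part of this, since 8007 promoters passed with the Huh7 arrays fitted alone. That fit also has more degrees of freedom: its standard errors with the degrees of freedom of the fit of all arrays gave 5918, and the reverse gave 2497. Smaller standard errors and more degrees of freedom thus each gave calls without the other, and the standard errors gave more. The blocked fit, which keeps all PLC5 arrays, gave 435 enriched and 899 depleted. Its median standard error was larger than without the block (0.0734 against 0.0598), and the shares of spread and degrees of freedom were not separated there. In simulated data 29 of 183 calls of the fit with Huh7 alone were false under 1 setting of the spread and 40 of 225 under another. Both lines had the same spread there, unlike in the data.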

How the results depend on the processing

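At least 94.1% of probes per array were well above background in both channels. Settings with the scan date, 1 line alone, PLC5 replicate 2 or both Huh7 replicates turned in sign, and the replicate block with an estimated correlation were chosen after seeing the data. Where not stated, the cause of a change was not tested. The correction for base composition was not run, because no sequences were used here.

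Promoter counts without a block were 0 in both directions in each line and between lines in limma (at an unadjusted p under 0.05: 1767 and 2102 in Huh7, 75 and 368 in PLC5, 999 and 927 between lines). With the replicate block they were 435 enriched and 899 depleted in Huh7, 0 and 3 in PLC5, and 112 higher and 53 lower in PLC5 than in Huh7. With the scan date block they were 381 and 809, 0 and 2, and 95 and 45. The Huh7 arrays alone gave 3943 and 4064. The mean of the highest 3 neighbouring probes gave 4649 and 6 in Huh7, because taking the highest probes lifts values by construction, and CNR1 in Huh7 turned from -0.011 to 0.68 with it. With PLC5 replicate 2 turned in sign there were 1284 and 1590 in Huh7, 1 enriched in PLC5, and 1376 higher and 730 lower between lines. Turning PLC5 replicate 1 instead, which was not run, would reverse the PLC5 signs. Leaving out 1 replicate at a time gave 0 to 3943 enriched and 2 to 4064 depleted in Huh7, 0 to 3943 and 0 to 2698 in PLC5, and 2 to 4373 higher and 0 to 3305 lower between lines, where a lone array was assumed to vary like the others.

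Depleted regions in Huh7 numbered 33 with the replicate block and 33 with the Huh7 arrays alone, against 0 without a block. Both fits share the Huh7 means, so the equal count follows from the minimum and does not show stability. Leaving out 1 replicate gave 0 to 10 bound and 33 to 59 depleted regions in Huh7, and 0 to 28 and 0 to 72 in PLC5. Of the 21 lists, 9 passed in Huh7, 9 in PLC5 and 4 between lines, and 0, 0 and 0 with an estimated correlation, with or without the replicate block. With PLC5 replicate 2 turned in sign 9, 12 and 2 passed, and 0, 0 and 0 with an estimated correlation. On simulated lists, whose promoters were drawn independently, that test found 0 of 5. Between 7 and 9 lists passed in Huh7, 6 and 12 in PLC5, and 5 and 10 between lines when 1 replicate was left out. The correlation of the Huh7 replicates was 0.80 with loess and 0.85 with bright probes, and that of the PLC5 replicates -0.34 with loess, -0.42 with bright probes and -0.41 with the series matrix. The number of promoters enriched in both lines ranged from 0 to 634 when 1 replicate was left out. Among the values of single named promoters over all settings, 1469 stayed within the replicate spread and on their side of the threshold, 389 moved by more, 270 newly passed in the same direction and 30 newly passed in the opposite one. Part of the 1469 was fixed in advance, because leaving out 1 of 2 replicates cannot move a mean beyond that spread. Blocks, a variance trend, separate slides, a fold minimum and 1 line alone leave the value and its sign unchanged. The sign differed from the reported one in 18 of 420 values with 1 replicate left out, 133 of 315 with arrays turned in sign and 75 of 1423 in the other settings.

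Both Huh7 replicates turned in sign gave 0 promoters in each direction without a block (2102 above and 1767 below 0 in Huh7 at an unadjusted p under 0.05 in limma, and 844 higher and 1788 lower between lines). With the replicate block as well there were 809 enriched and 381 depleted in Huh7, 2 depleted in PLC5, 76 higher and 352 lower between lines, and 33 bound regions in Huh7. Between lines 11 lists passed with or without the block, and 0 in each comparison with an estimated correlation. Named promoters that passed with the opposite sign then lay in Huh7 at -0.47 (POMGNT1), -0.46 (KDELR1), -0.40 (TMEM116), -0.38 (ACA3), -0.36 (C10orf65), -0.32 (TMEM111), -0.26 (AKAP14), 0.72 (RBMY1J), 0.52 (OVOL2), 0.44 (SLC1A2), 0.46 (HS6ST3), 0.51 (FRAS1), 0.43 (LPAL2), 0.23 (TAS2R48), 0.48 (hsa-mir-513-1), 0.74 (CCND2), 0.47 (PRICKLE1) and 0.27 (WNT1). Between lines they lay at 0.46 (POMGNT1), 0.47 (KDELR1), 0.42 (TMEM116), -0.65 (RBMY1J), -0.50 (OVOL2), -0.45 (SLC1A2), -0.50 (HS6ST3), -0.48 (FRAS1), -0.73 (hsa-mir-513-1), -0.58 (CCND2) and -0.45 (PRICKLE1). The signs in Huh7 turn by construction.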

Other observations

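The tests of the 2 gene families below were chosen after ranked lists were seen, and the chromosome and position profiles were not tested. Keratin-associated proteins, the matrix proteins of hair, had a median of -0.15 over 34 promoters in Huh7, which turned to 0.038 with normexp, and 25 of the 34 lay below 0 in both replicates (camera adjusted p = 5.12e-07, and 0.0792 with an estimated correlation). In PLC5 their median was -0.081, and -0.018 with normexp, with 21 below 0 in both replicates (adjusted p = 3.88e-08, and 0.0792 with an estimated correlation). Bitter taste receptors (TAS2R) had a median of -0.079 over 18 promoters in PLC5 and -0.0078 with normexp, with 9 below 0 in both replicates (adjusted p = 6.85e-05, and 0.187 with an estimated correlation). In Huh7 it was -0.12, which turned to 0.0047 with normexp, with 15 below 0 in both (adjusted p = 7.69e-05, and 0.187 with an estimated correlation).

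By position, Huh7 probes 0 to 500 bp downstream of the transcription start averaged 0.034 and 0.035 in the 2 replicates, against -0.059 and -0.030 at 5000 to 3000 bp upstream. In PLC5 replicate 1 the highest mean was 0.047, at 1000 to 500 bp upstream, and in replicate 2 it was 0.026, at 0 to 500 bp downstream. By chromosome, promoters on chromosomes 22 and 19 averaged 0.037 and 0.030 in Huh7 replicate 1 and 0.068 and 0.051 in replicate 2, and those on chromosomes 18 and 13 averaged -0.082 and -0.071, and -0.062 and -0.052. Chromosome Y lay lower still, at -0.086 and -0.22. In PLC5 replicates 1 and 2 it averaged -0.20 and 0.020, so the lower value of each line came from the second scan date. Of the 32 depleted Huh7 regions whose lowest window reached -1, after merging at the 1.5-fold minimum, 17 lay on chromosome Y. Of the 15 elsewhere, PLC5 replicate 1 lay above 0 in 13 and PLC5 replicate 2 in 4. With the block and the 1.5-fold minimum, PLC5 had 10 enriched and 45 depleted regions. The furthest from 0 off chromosome Y were near OR1D2 (0.85) and DMD (-0.86), chosen after their values were seen.

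A hypothesis from the ranked lists was that families of tissue-restricted genes, like olfactory receptors, were lower in the IP. The Huh7 keratin-associated proteins met it at -0.149 but not under normexp, so their direction stays open. The PLC5 taste receptors met it at -0.0791 with the preset correlation but not with an estimated one (adjusted p = 0.187), and normexp brought their median to -0.0078. The background correction may set part of this pattern, because normexp brought the median of olfactory receptors in Huh7 from -0.15 to -0.0079, and brightness and base composition were not separated. The families were picked and tested on the same arrays, and no biological explanation was tested.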
